A study of Rattus norvegicus with 8 samples.

How the data were processed

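RNA of laser-captured orbital and global layer of adult rat extraocular muscle was amplified with a T7-based kit and hybridised to a 1-colour Affymetrix rat RAE230A array, per the labels. The deposited table holds 1 intensity per probe set and array on a linear scale, and the software that summarised the probes and any detection calls are not given in the sources used here. From the values, the authors had scaled each array: the 2% trimmed means of the 8 arrays differed by at most 0.0039%. As fixed before the data were examined, trimmed means within 1% meant that the values were used as deposited, with no further normalization. Values from amplified RNA depend on how evenly each transcript was amplified, and a scaling to one mean makes every level relative to the other transcripts of its array.

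Samples were grouped by layer from the source given in the labels, 4 per layer, and numbered in accession order within a layer. Captures of the same layer correlated with r of 0.938 to 0.961 across probe sets and captures of different layers with r of 0.908 to 0.941, where probe sets are not independent replicates. A pair of orbital captures (3 and 4) has nearly the same title, but they were no more alike than the other 5 orbital pairs, with an SD of the difference of their log2 values of 0.458 against 0.425 to 0.449, so all 8 captures were counted. The first principal component held 36.8% of the variance and separated the layers, and the second held 14.7% and set global capture 4 apart.

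Of 15923 probe sets, 57 controls were left out, and 9520 of the other 15866 were tested, those whose mean log2 value was at or above the 40th percentile (an intensity of 39.4). The test was lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3) on log2(intensity + 1), with layer as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are on this scale, and the size of those of dim probe sets depends on the pseudocount. Probe sets were named from the platform's annotation, which can be old. It gave 1 gene symbol for 12783 probe sets, several for 312 and none for 2771, of which the last 2 kinds were not named. Through a current gene table, 12748 of the 12783 were found and 0 symbols changed. Of the 705 probe sets called, 106 had no single gene name. No genome was used, so no coordinates are given.

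For gene lists, each gene was taken by its brightest tested probe set and tested with camera at a preset correlation of 0.01, then with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. Lists with fewer than 5 tested genes had no test. The 20 lists were fixed before the data were examined, from textbook knowledge of muscle fibres, metabolism and other cell types of the tissue, and some genes stand in several lists. Genes were named by a rule fixed at the same time: the 12 genes with the largest difference in each direction that passed and did not overlap between layers, all measured myosin heavy chains, and in every other list up to 4 members with the smallest p. This names 97 genes, and those not printed are covered by the counts of their lists. Atp2a2, Casq2, Mb, Tnni1, Myl2 and Pln lie outside the rule and were chosen after their values were seen, to complete the slow and cardiac genes that passed, and the alternatives were not run for them. The layer difference was compared between title prefixes by an interaction term in limma. Quality measures were compared by exact permutation tests, two-sided.

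The procedure was tested on simulated data for the comparison of 4 against 4 captures. Of 200 changed among 9520 probe sets, 69% were recovered at a log2 difference of 1 and 98% at 2, and 5 unchanged probe sets were called (2.91% of calls). A simulated list that was moved was recovered among 7163 genes, and 0 other lists were called. Simulated genes were drawn independently, while in the data the fast contractile list had an estimated correlation of 0.44. The simulation therefore does not show how often lists of correlated genes are called falsely with the preset correlation.

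Alternatives were quantile and cyclic loess normalization, pseudocounts of 16 and 64, no filter and a filter at the 60th percentile, eBayes without trend and with robust fitting, the prefix as a fixed or random block and with captures averaged per prefix, array weights, orbital captures 3 and 4 averaged as 1 sample, each prefix alone, each capture left out in turn, and for lists the mean over a gene's probe sets. Added after seeing the data were fits with orbital captures 1 and 2 alone, with global captures 2 and 3 alone, the ribosomal list without kinases, the Gapdh 3′ to middle ratio in the test of RNA shortening, the fit of Guca1a (log2, least squares) on layer and the mean signal of 6 rod genes, and the Schwann cell and nerve list and then all other cell-type lists in the pool to which extracellular matrix and endothelial genes were compared. The highest control probe set of each array served as a mark of background, and this was also chosen after seeing the data.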

Results

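Gene expression was measured in the 2 layers of adult rat extraocular muscle, the muscle that moves the eye. Its fibres lie in an orbital layer, which faces the bone of the orbit, and a global layer, which faces the globe. Tissue of each layer was cut out by laser microdissection, and 4 captures of the global layer and 4 of the orbital layer were each hybridised to 1 array of 15923 probe sets. The comparison asks which transcripts differ in level between the layers. The labels do not tie the captures to animals and do not give the number of animals. If captures share an animal, the p-values over captures given throughout are too small, and they measure only the spread between these captures. The median probe set intensity was between 58.8 and 66.3 on the 8 arrays, and the number of arrays limits the precision. Differences are given as log2 of the orbital over the global layer, with the standard error (SE) and n = 4 captures per layer, and adjusted p-values are those of limma with Benjamini-Hochberg adjustment.

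The orbital captures carried far more cardiac troponin T and sarcolipin transcript than the global captures, and far less transcript of several genes of fast fibres. Tnnt2, the troponin T of heart and embryonic skeletal muscle, had an intensity of 783 ± 189 (SD, n = 4) in the orbital layer and 24.9 ± 31.3 in the global layer, a log2 difference of 5.93 ± 0.75 (SE, adjusted p = 0.000403). In the global captures Tnnt2 was under the highest control probe set of the array in 3 of 4, so the size of this difference rests on signal near background. It was between 3.29 and 6.76 over the alternatives. Sln, a small inhibitor of the sarcoplasmic reticulum calcium pump, reached 2310 ± 1181 in the orbital and 181 ± 184 in the global layer (4.08 ± 0.54, adjusted p = 0.000521). In the other direction Myom2, a protein of the sarcomere M band, had 215 ± 277 in the orbital and 3403 ± 1548 in the global layer (-4.59 ± 0.56, adjusted p = 0.000307). Aqp4, a water channel of the fast fibre membrane, had 71.5 ± 27.2 in the orbital and 1061 ± 272 in the global layer (-3.91 ± 0.25, adjusted p = 7.59e-06).

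Of 9520 probe sets tested, 705 differed between the layers at an adjusted p under 0.05, 372 higher in the orbital and 333 higher in the global layer. Of these, 240 differed at least 2-fold, 121 higher in the orbital and 119 higher in the global layer. All 4 captures of one layer lay above all 4 of the other for 1339 probe sets (14.1% of those tested, where chance gives 2.86%). Counting each gene once, by its brightest probe set, 550 of 7163 genes differed, 293 higher in the orbital and 257 higher in the global layer. The count of probe sets was 468 without global capture 3, 363 with orbital captures 1 and 2 alone against the 4 global captures, and 335 with global captures 2 and 3 alone against the 4 orbital captures. The ratio of the 3′ to the 5′ Gapdh probe set, which rises as RNA is shortened, was 8.41 ± 3.21 (SD, n = 4) in the orbital and 5.79 ± 0.478 in the global captures (exact permutation test, two-sided, p = 0.114; 0.343 after Benjamini-Hochberg adjustment over 6 measures), and it was highest in orbital captures 3 (12.9) and 4 (8.64). The Gapdh 3′ to middle ratio was 6.27 ± 0.816 in the orbital and 5.39 ± 0.259 in the global captures (exact permutation p = 0.0857; 0.343 adjusted). The 3′ to 5′ ratio of beta actin was 8.43 ± 0.536 in the orbital and 8.98 ± 1.43 in the global captures (exact permutation p = 0.543).

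Genes were taken by their brightest tested probe set and ranked among those that passed without overlap between layers. The 12 genes furthest above the global layer also held Myh3, Tubb6 (a tubulin), Boc (a cell surface receptor of myogenic cells) and Ecrg4. The others were Myh6, Nbl1, Mt3 (a metallothionein), Guca1a, Hopx and LOC102553868. Boc rose from 135 ± 46.5 in the global to 869 ± 154 in the orbital layer (2.72 ± 0.22, adjusted p = 2.13e-05), and Hopx, a homeodomain protein of heart muscle, from 339 ± 147 to 1295 ± 303 (2.01 ± 0.27, adjusted p = 0.000600). The log2 difference was 2.88 for LOC102553868, 2.81 for Tubb6, 2.63 for Ecrg4, 2.26 for Nbl1, 2.12 for Mt3 and 2.05 for Guca1a. In the global captures Tubb6 and Nbl1 were each under the highest control probe set of the array in 3 of 4, LOC102553868 in 2 and Sln and Mt3 in 1, so these sizes and their rank are uncertain. Over the alternatives the difference of Tubb6 was between 1.08 and 3.65 and that of Nbl1 between 0.94 and 2.99. That of LOC102553868 was between 1.54 and 3.40 and that of Mt3 between 1.34 and 2.46. Guca1a is an activator of guanylate cyclase known from photoreceptors, and transcripts of other photoreceptor genes were present in some captures of both layers, with Sag between 2.2 in global capture 2 and 802 in orbital capture 2. The 12 genes furthest below the global layer by the same ranking also held Dhrs7c, Actn3, Mybpc2, Pvalb, Scd, Car3, Fbp2, Mybphl, Gpd1 and Cd55. Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum, had 128 ± 70.2 in the orbital and 1890 ± 240 in the global layer (-4.06 ± 0.34, adjusted p = 2.13e-05), and Car3, the carbonic anhydrase of muscle, 623 ± 322 and 5256 ± 852 (-3.25 ± 0.34, adjusted p = 0.000103). A second probe set of Car3 also differed (-2.50). Scd, a fatty acid desaturase, differed by -3.29, Fbp2, the fructose bisphosphatase of muscle, by -3.18, Mybphl by -3.14 and Cd55 by -2.21. Fbp2 was under the highest control probe set in 1 orbital capture, and its difference was between -3.98 and -1.83 over the alternatives.

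**Figure D1:**
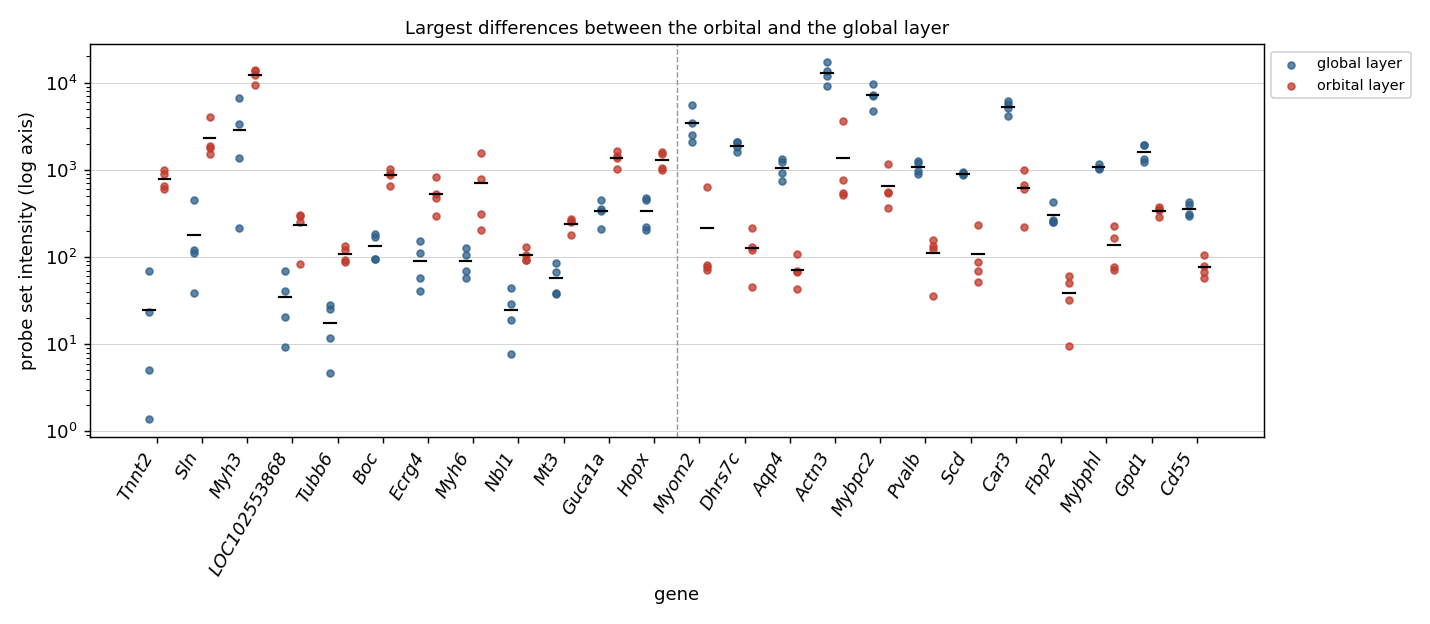
Probe set intensity (log axis) of the 12 genes furthest above and the 12 furthest below the global layer by each gene's brightest tested probe set, left and right of the dashed line. Each point is 1 capture (blue global, red orbital, n = 4 per layer) and each black bar the mean of a layer. The 24 genes were chosen among those that passed and whose points do not overlap between layers, so the lack of overlap is no result.

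The myosin heavy chains, the motor proteins by which muscle fibre types are told apart, went in both directions. Of 11 tested, 4 rose in the orbital layer (Myh3, Myh6, Myh8 and Myh10), 2 fell (Myh7 and Myh11) and 5 did not pass. Embryonic Myh3 had 12239 ± 2023 (SD, n = 4) in the orbital and 2892 ± 2807 in the global layer (2.92 ± 0.74, adjusted p = 0.0290), and neonatal Myh8 had 9071 ± 1785 and 3124 ± 930 (1.56 ± 0.21, adjusted p = 0.000506). Cardiac alpha Myh6 had 714 ± 611 and 90.3 ± 32.9 (2.61 ± 0.49, adjusted p = 0.00532), while slow Myh7 had 3007 ± 1105 and 10362 ± 1294 (-1.84 ± 0.21, adjusted p = 0.000158). Fast Myh4 differed by -1.12 ± 0.32 (adjusted p = 0.0515) and passed under 9 of 25 alternatives, among them the prefix as a replicate block (0.0475). Myh13, the isoform of extraocular muscle, differed by 0.24 ± 0.17 (adjusted p = 0.468), Myh2 by 0.25 ± 0.27 and Myh1 by -0.09 ± 0.27. Non-muscle Myh10 differed by 0.58, Myh9 by 0.29 without passing, and smooth muscle Myh11 by -1.39. With the adjustment over the list alone, 4 were higher and 3 lower, and the list as a set gave an adjusted p of 0.470 (camera). The myosin genes of skeletal and heart muscle are closely similar in sequence, so signal shared between paralogs leaves their separate levels uncertain. The call of Myh3 was lost without global capture 1 or any 1 of the 4 orbital captures (adjusted p 0.0511 to 0.0784). With all 8 captures it was also lost with robust eBayes (0.179), without trend (0.0663), without the filter (0.0600) and with orbital captures 3 and 4 averaged (0.0717). The difference of Myh3 was between 1.36 and 4.01 over the alternatives. The Myh6 call was lost with robust eBayes (0.0632), and that of Myh10 without global capture 3 or orbital capture 3 (0.0517 and 0.0555).

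**Figure D2:**
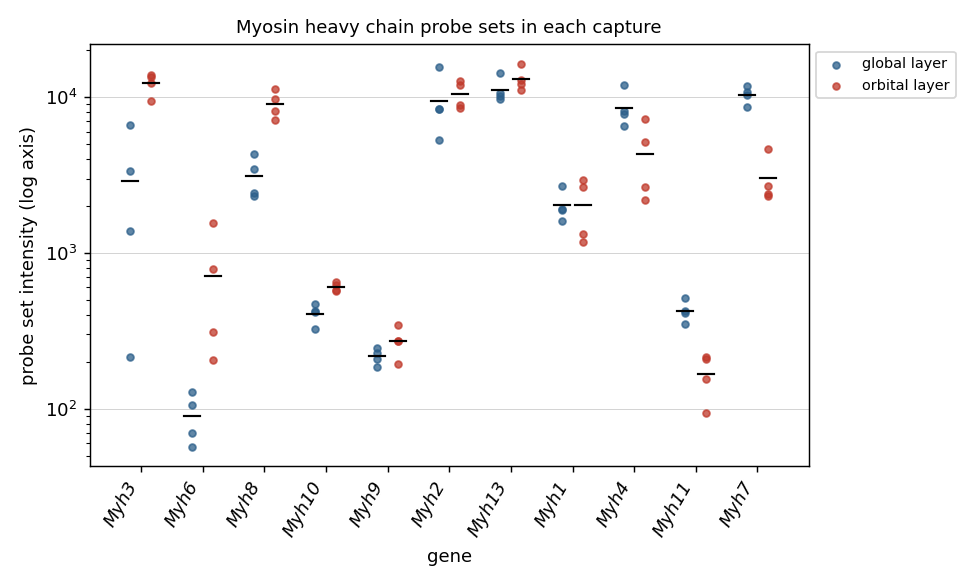
Probe set intensity (log axis) of the 11 tested myosin heavy chains, with 1 point per capture (blue global, red orbital; n = 4 per layer) and black bars at the layer means, ordered by log2 difference. Myh8 lies at a mean of 9071 in the orbital and 3124 in the global layer, Myh7 at 3007 and 10362, and the points of Myh13 overlap.

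Several genes of fast contraction and calcium handling were lower in the orbital layer. Of 16 tested, 7 fell, none rose (0) and 9 did not pass, with 10 lower and 0 higher adjusted over the list alone and a median log2 difference of -0.68. Actn3, the alpha actinin of fast fibres, had 1363 ± 1521 in the orbital and 12933 ± 3377 in the global layer (-3.75 ± 0.48, adjusted p = 0.000425). Mybpc2, fast myosin binding protein C, differed by -3.54 (and by -3.16 at a second probe set), Pvalb, the calcium buffer parvalbumin, by -3.44 and Myoz1 by -1.37. The list gave an adjusted p of 7.04e-08 in camera with the preset correlation, and an adjusted p of 0.277 with an estimated correlation. Of the 15 genes of excitation-contraction coupling and the fibre membrane, 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.49. Cacng1, a subunit of the muscle calcium channel, differed by -1.83 ± 0.24 (adjusted p = 0.000446), and by -1.96 to -0.88 over the alternatives. It was under the highest control probe set in 1 orbital capture. The junctophilins Jph1 and Jph2 differed by -0.90 and -0.86. Cacna1s, the pore of that channel, differed by -0.78 (adjusted p = 0.0203), a call lost without global capture 1 or 3 or orbital capture 2 or 4 (0.0503 to 0.0654). That list gave an adjusted p of 1.55e-05, and an adjusted p of 0.185 with an estimated correlation.

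Slow and cardiac contractile genes split. Of 18 tested, 6 rose, 5 fell and 7 did not pass, with 8 higher and 5 lower adjusted over the list alone. Those that rose were Tnnt2, Sln, Myh6, Atp2a2 (1.19), Casq2 (1.01) and Mb (0.82), and those that fell were Myl3, Myh7, Tnni1 (-1.62), Myl2 (-1.13) and Pln (-1.08). Myl3, a slow and ventricular myosin light chain, had 272 ± 118 (SD, n = 4) in the orbital and 1016 ± 241 in the global layer (-2.004 ± 0.317, adjusted p = 0.00189). The list gave an adjusted p of 0.676 in camera.

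Developmental and regenerative muscle genes were higher in the orbital layer as a list with the preset correlation only, with 4 of 16 rising (Tnnt2, Myh8, Myf6 and Myh3), 0 falling and a median of 0.51 (8 higher and 0 lower adjusted over the list alone). Tnnt2 and Myh3, also in other lists, gave the largest differences, and Myf6, a myogenic regulator, differed by 0.64 ± 0.15 (adjusted p = 0.0175), a call lost without orbital capture 1 or 2 or global capture 3 (0.0524 to 0.0575). The list gave an adjusted p of 0.00247 in camera, and an adjusted p of 0.185 with an estimated correlation. Of 9 neuromuscular junction genes, 1 fell and 0 rose (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.179). The 1 that fell was Ky (-1.49 ± 0.29, adjusted p = 0.00658), whose second probe set differed by -0.72 without passing. The acetylcholine receptor subunits Chrna1 and Chrnd differed by 1.05 (adjusted p = 0.0566) and 0.94 (adjusted p = 0.0855), and Colq by 0.47.

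Many glycolysis and glycogen genes were lower in the orbital layer, and the lists of mitochondrial oxidation did not pass. Of 19 glycolysis and glycogen genes, 10 fell, 0 rose and 9 did not pass (12 lower and 1 higher adjusted over the list alone), with a median of -0.56. Gpd1, glycerol-3-phosphate dehydrogenase, had 340 ± 35.5 (SD, n = 4) in the orbital and 1608 ± 372 in the global layer (-2.22 ± 0.16, adjusted p = 2.08e-05). Pgm1, phosphoglucomutase, differed by -1.78 at each of its probe sets, Tpi1 by -0.96 and Pfkfb1 by -0.73. The list gave an adjusted p of 7.04e-08, and an adjusted p of 0.277 with an estimated correlation. Of 76 oxidative phosphorylation genes 2 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.03, camera adjusted p = 0.659), namely Cox6a1 (0.64 ± 0.13, adjusted p = 0.0105) and Cox8a (0.46 ± 0.13, adjusted p = 0.0490). The Cox8a call was lost on leaving out any 1 capture other than orbital capture 3 (0.0665 to 0.133), and without orbital capture 3 the list passed (adjusted p = 0.0179). Of 19 citric acid cycle genes 1 rose and 0 fell (1 and 0 over the list alone, camera adjusted p = 0.494). That was Ogdh (0.50 ± 0.13, adjusted p = 0.0361), whose call was lost on leaving out any 1 capture other than global capture 3 (0.0635 to 0.0913). Of 27 genes of fatty acid uptake and oxidation 2 rose and 0 fell (2 and 0 over the list alone, camera adjusted p = 0.413). They were the carnitine carrier Slc25a20 (1.001 ± 0.181, adjusted p = 0.00403) and Lpl, lipoprotein lipase (0.78 ± 0.21, adjusted p = 0.0406), and the Lpl call was lost on leaving out any 1 capture other than global capture 2 or orbital capture 3 (0.0598 to 0.0954).

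**Figure D3:**
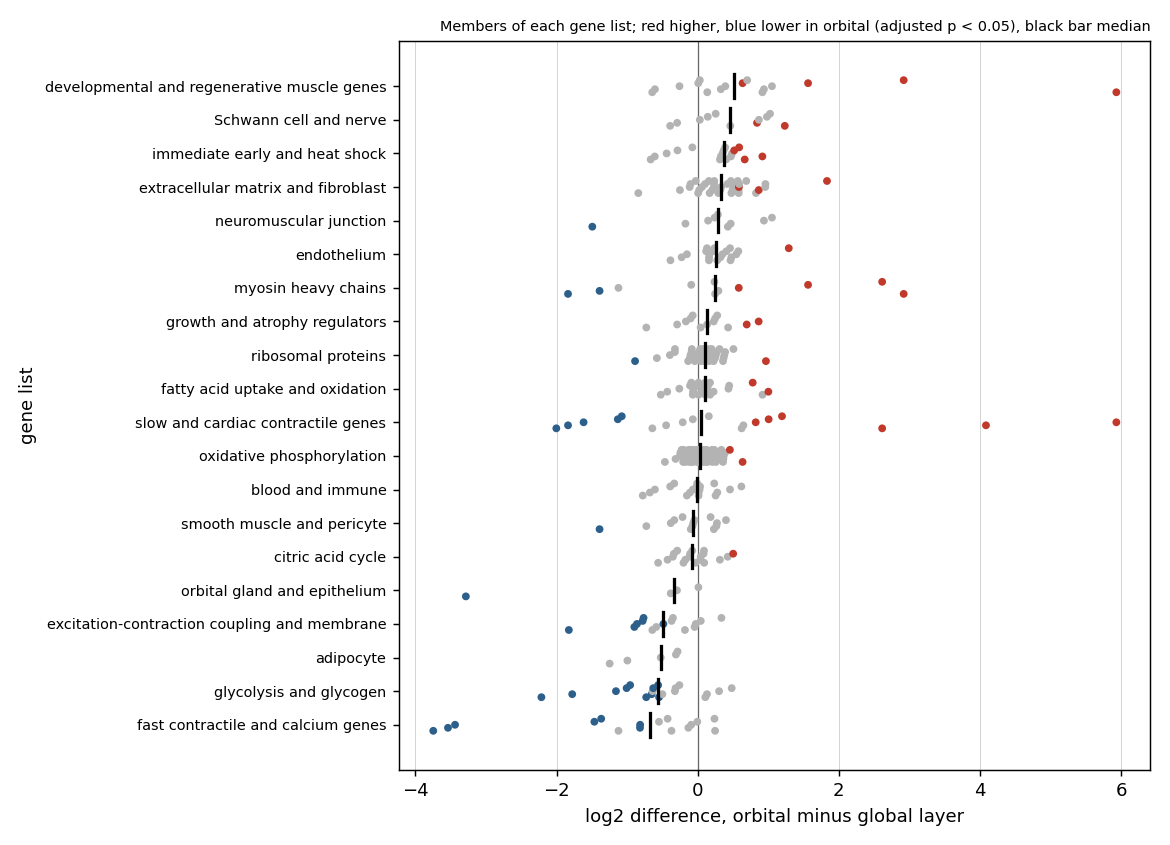
Log2 difference, orbital minus global layer, of each tested member of the 20 gene lists, 1 point per gene, with a black bar at the median of each list. Red and blue points are genes higher and lower in the orbital layer at an adjusted p under 0.05, and the medians run from -0.68 for fast contractile and calcium genes to 0.51 for developmental and regenerative muscle genes.

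Among lists that mark other cell types, those of extracellular matrix, endothelial and adipocyte genes passed in camera with the preset correlation and none (0) with an estimated one, and few of their members passed. Of 35 extracellular matrix and fibroblast genes, 3 rose and 0 fell (13 higher and 1 lower adjusted over the list alone), with a median of 0.33. Thbs4, a thrombospondin of tendon and muscle matrix, had 595 ± 288 (SD, n = 4) in the orbital and 164 ± 81.0 in the global layer (1.83 ± 0.38, adjusted p = 0.0104). That call was lost with robust eBayes (0.0646) and with global captures 2 and 3 alone (0.103). Fmod differed by 0.86 (adjusted p = 0.0472) and Igfbp7 by 0.58 (adjusted p = 0.0450), and each of these calls was lost on leaving out any 1 of 6 captures (Fmod 0.0717 to 0.141, all but global capture 3 and orbital capture 4; Igfbp7 0.0666 to 0.131, all but global capture 4 and orbital capture 1). The list gave an adjusted p of 8.78e-05, and an adjusted p of 0.277 with an estimated correlation. Of 20 endothelial genes 1 rose and 0 fell (3 and 0 over the list alone; median 0.26, adjusted p = 0.0121, and an adjusted p of 0.474 with an estimated correlation). That gene was Eng (1.29 ± 0.30, adjusted p = 0.0193; 0.57 to 1.51 over the alternatives, with 1 global capture under the highest control probe set), lost without global capture 1 or 3 or orbital capture 2 or 3 (0.0512 to 0.0693), and the list did not pass without orbital capture 4 (0.0663), with orbital captures 1 and 2 alone (0.210) or with global captures 2 and 3 alone (0.0680). Of 5 adipocyte genes 0 rose and 0 fell over all probe sets (3 lower over the list alone; median -0.52, adjusted p = 0.0101, and an adjusted p of 0.277 with an estimated correlation). Among them Pck1 differed by -1.25 (adjusted p = 0.0810), Thrsp by -0.997 (1 orbital capture under the highest control probe set) and Dgat2 by -0.52, and the list did not pass with global captures 2 and 3 alone (0.0531). Against the mean of the other global captures, the median of the adipocyte list was -0.73 in global capture 3 and 0.49 in global capture 4.

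Markers of smooth muscle, nerve and blood cells did not pass as lists. Of 14 smooth muscle and pericyte genes 1 fell, Myh11, and 0 rose (1 and 0 over the list alone, adjusted p = 0.402), and Tagln differed by -0.73 (adjusted p = 0.0977). Of 11 Schwann cell and nerve genes 2 rose and 0 fell (2 and 0 over the list alone; median 0.46, adjusted p = 0.105). They were Cnp (0.84 ± 0.19, adjusted p = 0.0140), lost without orbital capture 3 (0.0512), and Nefm, neurofilament medium chain (1.23 ± 0.31, adjusted p = 0.0291), lost without global capture 1 or 4 or orbital capture 1, 2 or 3 (0.0718 to 0.0829). With global captures 2 and 3 alone Nefm differed by 0.60 (adjusted p = 0.223), and over the alternatives by 0.60 to 1.57. Against the mean of the other global captures, the median of the Schwann cell and nerve list was 0.75 in global capture 4 and -0.62 in global capture 3. The list passed without global capture 4 (adjusted p = 0.00471), without orbital capture 4 (0.0457), with orbital captures 1 and 2 alone (0.0294) and with global captures 2 and 3 alone (0.00603). Of 19 blood and immune genes 0 rose and 0 fell (0 and 0 over the list alone; median -0.01, adjusted p = 0.571), and Cd74 differed by -0.39. Of 4 orbital gland and epithelium genes, too few for a test as a list, Scd fell and 0 rose, while Prlr differed by -0.38, Krt8 by -0.29 and Fasn by 0.01.

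Of the lists of growth regulators, stress genes and ribosomal proteins, that of immediate early and heat shock genes passed, with the preset correlation only. Of 13 growth and atrophy regulators 2 rose and 0 fell (2 higher and 1 lower over the list alone, adjusted p = 0.513). They were Igfbp6 (0.86 ± 0.19, adjusted p = 0.0141) and Igf1, insulin-like growth factor 1 (0.69 ± 0.18, adjusted p = 0.0367). The Igfbp6 call was lost without orbital capture 3 (0.0512). That of Igf1 was lost on leaving out any 1 capture other than global capture 2 or orbital capture 4 (0.0640 to 0.105). A second, dimmer probe set of Igf1 differed by 0.87 (adjusted p = 0.00653), and the alternatives were not run for it. Of 17 immediate early and heat shock genes 4 rose and 0 fell (6 and 0 over the list alone), with a median of 0.37 and an adjusted p of 0.0164 (adjusted p of 0.185 with an estimated correlation, and 0.117 with global captures 2 and 3 alone). They were Hsph1 (0.92), Hspa1a (0.52), Atf3 (0.59) and Hspb1 (0.67), of which each call was lost on leaving out single captures: Hsph1 without global capture 1 or 3 (0.0598 and 0.0650), Hspa1a (0.0546 to 0.0795) and Hspb1 (0.0967 to 0.143) without any 1 of global captures 1, 2 and 3 and orbital captures 1 and 3, and Atf3 without any 1 capture other than global capture 2 or orbital capture 2 (0.0559 to 0.122). Of 46 genes taken as ribosomal proteins by name, 1 rose, Rpl3 (0.97 ± 0.18, adjusted p = 0.00587), and 1 fell, Rps6kb1 (-0.89 ± 0.16, adjusted p = 0.00358), which is a kinase and not a ribosomal protein (1 and 1 over the list alone, camera adjusted p = 0.184, and 0.0461 without global capture 2). Without the 4 kinases caught by the name pattern, 1 of 42 rose and 0 fell.

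Of the 20 lists, 19 were tested and 8 passed in camera with the preset correlation, 4 higher and 4 lower in the orbital layer. The counts given for lists are of members that were tested. With an estimated correlation 0 passed (limma camera; lowest adjusted p = 0.185), and 3 had an unadjusted p under 0.05. Besides Myh3, Myh6 and Thbs4, with all 8 captures in the fit the calls of Atf3, Fmod, Igfbp7, Hspb1, Cox8a, Nefm, Igf1, Lpl, Ogdh, Hspa1a and Hsph1 were lost under at least 1 of 13 other settings (adjusted p 0.0508 to 0.0984). In turn 18 of the named genes that did not pass did so under at least 1 of the 25 alternatives, most often Myh4 (9), Trim63 (8), Chrna1 (7) and Dcn (7). All of them but Flt1 passed with captures averaged per prefix, a fit that leaves very few residual degrees of freedom. Cdkn1a, Egr2, Idh3b, Mbp and Thrsp passed only there.

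The titles carry a prefix, R2 or R3, with 2 captures of each layer under each, and the labels do not say what it stands for. The layer difference was compared between the prefixes by an interaction term. In limma 0 probe sets passed (lowest adjusted p = 0.9999), and 290 had an unadjusted p under 0.05, where chance gives 476. Within R2 alone 106 probe sets differed between the layers, and within R3 alone 166, with 2 captures per layer in each. The signal of a spike-in control, CreX, was 10348 ± 943 (SD, n = 4) under R3 and 5921 ± 518 under R2 (exact permutation test, two-sided, p = 0.0286, the smallest this design allows, and 0.171 after Benjamini-Hochberg adjustment over 6 measures).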

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

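The tests of a smaller share of muscle fibre RNA and of Guca1a at equal rod gene signal, and the Gapdh 3′ to middle ratio in the test of RNA shortening, were chosen only after the result was seen.

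Among 206 groups of 4 captures looked at, 7 held a capture far from the others, where chance gives 10.3. Myom2 was at 630.9 in orbital capture 3 and between 71.6 and 81.2 in the other orbital captures. LOC102553868 was at 83.8 in orbital capture 3 and between 252.4 and 299.8 in the others. Pvalb was at 35.9 in orbital capture 1, against 122 to 157. Fbp2 was at 429.9 in global capture 3, against 251 to 269, and Mybphl at 1181.8 in that capture, against 1024 to 1043. Cnp was at 188.6 in orbital capture 4, against 309 to 340, and Nefm at 145.1 in that capture, against 223 to 238.

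The layers differed at 705 probe sets. Of the 35 splits of the 8 captures into 4 and 4, the real split alone (1) gave as many and the highest other gave 1. No smaller share is possible with 35 splits, so chance is unlikely but not excluded for this count. Every other split mixes the layers, so a layer difference widens the spread within its groups. The splits also treat the captures as exchangeable, although some may share an animal. The number of gene lists does not stand out: 9 of the 35 splits gave at least the real number of 8, the highest other gave 10, and the split by title prefix gave 7. After cyclic loess 95.2% of the 705 stayed called with the same sign, which argues against signal-dependent scaling. The probe sets called under R3 showed under R2 a median share of 0.817 of their difference (bootstrap interval over probe sets 0.778 to 0.870). They were chosen by their call under R3, which tends to overstate their R3 difference, so a share under 1 can arise from this choice alone. Probe sets are also not independent, so the bootstrap interval is probably too narrow. It lay above the share of the layer shift of the Gapdh 3′ to 5′ ratio (log2 0.14 under R2 and 0.80 under R3, a share of 0.18). It did not lie above that of the 3′ to middle ratio (0.19 and 0.23, a share of 0.81). The actin ratio went the other way (-0.02 and -0.14). The measures disagree, and the choice of probe sets can lower the share. RNA shortening therefore cannot be told apart from a difference between the layers themselves. That difference stays open and was not tested apart from the captures that carry it.

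Extracellular matrix genes and endothelial genes were higher in the orbital captures as lists with the preset correlation, and with an estimated correlation neither passed (adjusted p = 0.277 and 0.474). A smaller share of muscle fibre RNA would raise markers of all other cell types alike. The extracellular matrix median exceeded the pooled median of the blood, immune and smooth muscle lists by 0.379 (bootstrap interval over genes 0.212 to 0.607). The endothelial median exceeded it by 0.303 (0.153 to 0.496). These intervals resample genes and not captures, and the genes are not independent (estimated correlation 0.17 and 0.19). They do not measure the spread between captures, so they cannot decide on a smaller fibre share. The Schwann cell and nerve list goes with a smaller share (median 0.46). With it in the pool the excess was 0.320 (0.0964 to 0.553) and 0.244 (0.0279 to 0.440). Neither the extracellular matrix nor the endothelial list exceeded the Schwann list alone (-0.13 and -0.20). With the adipocyte and the orbital gland and epithelium lists also in the pool, the excess was 0.379 (0.215 to 0.629) and 0.303 (0.151 to 0.528). The adipocyte list, of 5 tested genes, was lower in the orbital captures (median -0.52). A smaller share as all or part of the cause, more connective tissue or vessels in the orbital captures, or more transcript per cell, stays open.

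Rod photoreceptor transcripts appeared in captures of both layers, with Sag from 2.2 in global capture 2 to 802.3 in orbital capture 2. For 5 photoreceptor genes whose values had not been looked at, deviations from the layer mean were correlated across the 8 captures with those of 6 rod genes that had stood out. The median correlation was 0.847, which 0% of 10000 random lists matched on expression reached, although Pde6h did not follow (-0.34). The random lists were drawn gene by gene, so they need not hold genes that vary together. Retinal RNA carried into some captures may be the source. The 6 rod genes were higher in the orbital captures too, by a mean of 1.43 and up to 2.62 for Sag, though 0 of them passed. With their mean signal in the fit Guca1a still differed by 1.91 (95% interval 1.09 to 2.73, before 2.05), while each rod gene, fitted on the other 5, fell to between -0.24 and 0.35 with an interval that held 0, which argues against carried retinal RNA as the whole cause of the Guca1a difference. In orbital captures 1 and 3, where 6 of 6 rod genes were lower than in global capture 1 and 5 of 6 lower than in global capture 4, Guca1a was still at least 2.28-fold higher than in those global captures, and a difference of the muscle layers in Guca1a stays open.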

How the results depend on the processing

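The fits with orbital captures 1 and 2 alone and with global captures 2 and 3 alone were chosen after seeing the data. The count of 705 probe sets stayed within 1.5 times under both normalizations, both pseudocounts, both filters, both variance priors, array weights and the averaging of orbital captures 3 and 4 (506 to 753). It was 106 in R2 alone and 166 in R3 alone, which hold fewer samples, 363 with orbital captures 1 and 2 alone, 335 with global captures 2 and 3 alone, and 468 (without global capture 3) to 726 on leaving out 1 capture. Title prefixes do not pair the captures as far as the labels say. Deviations from the layer mean correlated by 0.0517 on average between captures of different layers with the same prefix. The mean of -0.0517 between prefixes mirrors that value, since deviations sum to 0 within a layer, and adds no evidence. Of 8 captures, 7 correlated best with their own prefix in the other layer, over only 2 prefixes. With the prefix as a replicate block the count was 745 and 8 lists passed, as a random block 651, and with captures averaged per prefix and the replicate block 1229, for which the cause was not tested. The fit with averaged captures leaves very few residual degrees of freedom, so calls gained only there are weak. With the estimated correlation 0 lists passed: adjusted p was 0.277 for fast contractile, glycolysis, extracellular matrix and adipocyte genes, 0.185 for coupling, developmental and immediate early genes, and 0.474 for endothelium. On leaving out 1 capture, 8 to 9 lists passed. Endothelium gave 0.210 with orbital captures 1 and 2 alone and 0.0680 with global captures 2 and 3 alone, where adipocyte genes gave 0.0531 and immediate early genes 0.117. Schwann cell and nerve genes passed with the filter at the 60th percentile (0.0262), captures averaged per prefix (0.00107), array weights (0.0404), orbital captures 1 and 2 alone (0.0294) and global captures 2 and 3 alone (0.00603), and ribosomal proteins with quantile (0.0147) and loess normalization (0.0284). The cause of these changes was not tested. On leaving out 1 capture, adjusted p was 0.000818 to 0.0663 for endothelium, 0.00471 to 0.273 for Schwann cell and nerve, 0.0179 to 0.870 for oxidative phosphorylation and 0.0461 to 0.431 for ribosomal proteins. Of the 97 genes named by the rule, 58 passed, 21 of them under all 25 alternatives and 40 whichever capture was left out, and 0 reversed. With all 8 captures 14 of the 58 lost their call under at least 1 of 13 settings, and 23 with orbital captures 1 and 2 or global captures 2 and 3 alone. For lists, robust eBayes and the random block were not run, since camera takes neither. Intensity over background limits the dim genes, and detection calls were not used here.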

Other observations

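The test of isoform pairs, and the genes of the next 2 paragraphs, were chosen only after values were seen, and the alternatives were not run for those genes.

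Single genes outside the fixed lists also differed, and no list or enrichment of them was tested. Bdh1, which oxidises 3-hydroxybutyrate, differed by 3.19 ± 0.49 (SE) at one probe set and 1.52 ± 0.17 at a brighter one (adjusted p = 0.00158 and 0.000131), and Oxct1, which activates acetoacetate, by 0.69 ± 0.14 (adjusted p = 0.00830). The catalytic calcineurin subunit Ppp3ca differed by -1.83 ± 0.18 and -1.18 ± 0.15 at its probe sets (adjusted p = 6.62e-05 and 0.000360) and the regulatory subunit Ppp3r1 by -0.70 ± 0.14 (adjusted p = 0.00686). The calcineurin regulators Rcan2 and Rcan1 differed by 1.15 ± 0.14 (adjusted p = 0.000327) and 0.82 ± 0.21 (adjusted p = 0.0335).

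Tmod4, which caps thin filaments, differed by -2.20 ± 0.19 (adjusted p = 3.31e-05) and Cmya5 by -1.82 ± 0.23 (adjusted p = 0.000391), while Myom1, an M band protein related to Myom2, differed by 0.81 ± 0.14 (adjusted p = 0.00381). Ampd1, the AMP deaminase of muscle, had 447 ± 84.6 (SD, n = 4) in the orbital and 1631 ± 273 in the global layer (-1.87; adjusted p = 3.16e-05). The mitochondrial glycerol-3-phosphate dehydrogenase Gpd2 differed by -2.15 ± 0.24 (adjusted p = 0.000141), and by -1.02 at a second probe set that did not pass (adjusted p = 0.0619). Higher in the orbital layer were Adamts1 (1.97 ± 0.18), Scg5 (1.71 ± 0.16) and Map2 (1.77 ± 0.32).

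A hypothesis is that a muscle isoform may be lower and another isoform of the same protein higher in the orbital layer. The other isoform is not always one from outside muscle, as Atp2a2 and Casq2 stand in the list of slow and cardiac contractile genes. Pgam2 differed by -0.63 and Pgam1 by 1.08, Eno3 by -0.56 and Eno1 by 0.71, Casq1 by -0.82 and Casq2 by 1.01, and Atp2a1 by -0.82 and Atp2a2 by 1.19, the 4 of 18 pairs in which both members passed in opposite directions. The difference, other isoform minus muscle isoform, was above 0 in 18 of 18 pairs. It can be above 0 without a lower muscle isoform and a higher other isoform. Ckb (-0.17) and Adss2 (-0.18) were not higher, and Eef1a2 (0.11) and Cox8b (0.23) were not lower. The count of 18 is no test, because for 16 of the pairs a member had already been seen when the pairs were written down. The other 2 pairs, Ckm with Ckb and Capn3 with Capn1, were both above 0 (2 of 2). In neither did the other isoform pass as higher (Ckb -0.17, Capn1 0.03). They are too few for an exact sign test (two-sided p = 0.5, the smallest for 2 pairs), so the hypothesis stays untested.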
